A study of Homo sapiens with 6 samples.

How the data were processed

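HCT116 cells transduced with a control shRNA (sh-Ctrl) or an shRNA against PNO1 (sh-PNO1), 3 samples per group, were profiled by the study on Affymetrix expression arrays from 100 ng of total RNA labelled as biotinylated cRNA, per the labels' protocols. The deposited values are intensities on a linear scale, 1 for each of 49395 probe sets and 6 arrays. Per the submitters' processing notes the authors used RMA, with no version given, which summarises the probes of a probe set and normalises between arrays. RMA usually returns log2 values, whereas the deposited intensities lay on a linear scale with nearly equal medians on every array, so log2 was taken here before any test; log2 values had been assumed when the tests were planned. Software, background step and genome build are not given in the sources used here, and scanner files were not used here. No detection calls were used. The 23 background probe sets had mean intensities of 2.52 to 802, the brightest being those of highest GC content, and the GC content of the other probe sets was not used here. So only the 974 genes with a group mean above all 23, 525 of which passed, are plainly above background at any GC content. The other 5660 genes that passed could not be judged 1 by 1, and folds of dim genes can be understated. Background rose steeply with GC content, with a mean log2 in sh-Ctrl of 1.34 for GC03, 5.04 for GC20 and 9.53 for GC25. The bound of 802 is therefore strict for probe sets of lower GC content, and a gene below it may still be above its own background. Normalisation that gives all arrays similar distributions removes any overall rise or fall of total messenger RNA, so every change is relative to the other genes of the same array. Groups and replicate numbers were taken from the sample titles.

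Probe sets were named through the platform's gene table. Of the 49395 probe sets 102 were controls, 44988 had 1 gene symbol, 1832 had several and 2473 were not listed there. Symbols were checked by gene identifier against the gene table of assembly GRCh38.p14, in which 44967 of the 1-symbol probe sets were found and 0 symbols changed; that table was used for names only. Each gene was represented by its probe set with 1 symbol and the highest mean over the 6 arrays, which gave 18132 genes, 11734 of them with 2 or more probe sets. Of 157 named genes that passed and have 2 or more probe sets, 71 had every probe set passing in the same direction. Where others did not, the text gives this for changes of 0.5 or more, and for smaller ones only in part.

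All genes were fitted in limma (version 3.58.1, R version 4.3.3) with lmFit and eBayes on log2 values, sh-PNO1 minus sh-Ctrl, over all 6 arrays with no covariate, and p-values were adjusted by Benjamini and Hochberg. A gene passed at an adjusted p under 0.05, and a 2-fold change was an absolute log2 value of at least 1 in such a gene. For PNO1 an exact two-sided permutation test was added. The 38 gene lists came from textbook knowledge and not from the study. Each was tested two-sided with limma's camera at its preset correlation between genes of 0.01, with adjustment over the 38 lists, then with the correlation estimated from the residuals, with camera on ranks, and with fry. Fry tests whether the genes of a list move one way on balance, or in its mixed form in either direction, and does not compare a list with other genes.

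The tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names PNO1, MDM2, CDKN1A and NOB1 in any case; the 12 largest increases and 12 largest decreases among genes that passed, whose groups did not overlap, with an official named symbol and a higher group mean above the 30th percentile of gene means; and in each list up to 4 members with the smallest adjusted p. One further gene of that rule, and the usual name of the list that holds CDKN1A and MDM2, are not reported here. Alternatives were the replicate number as a block, a mean-variance trend with a robust prior, array weights, quantile normalisation repeated, arrays shifted to equal medians or to equal means of housekeeping genes, the dimmest 30% of genes left out, probe sets averaged, the probe set with the largest interquartile range, every probe set tested, an adjusted p under 0.01, an unmoderated statistic, a test against a log2 change of 0.5 (treat), and each array left out in turn. An alternative without probe sets of the suffix _x_at or _s_at was chosen after seeing the data. Only these are meant below by probe sets that can match several transcripts, and those of other suffixes, such as _a_at, were kept.

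The limma step was tested on simulated data with the 18132 genes, 200 of them changed. For sh-PNO1 against sh-Ctrl it recovered 82.5% of changes of 0.5 on the log2 scale with 3.5% false calls, and 99.5% of changes of 1 with 6.1% false calls. In the data 6185 genes passed, with a median size of 0.31, so the gene test was not simulated at that number and size. In the list step, a list raised by 0.3 was recovered and 1 other list was called. Some lists share members, such as BBC3 in the raised list and the apoptosis list, so the other call need not be a false one. The simulated genes varied independently of each other, whereas the estimated correlation was 0.0656 in the raised list and 0.297 in the mitosis list. The simulation therefore does not show how camera behaves with correlated genes. Figures were drawn with matplotlib 3.10.9.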

Results

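Gene expression was measured in HCT116 cells, a human colorectal cancer cell line, 72 h after transduction with a lentivirus that carried a short hairpin RNA (shRNA) against PNO1 (sh-PNO1) or a control shRNA (sh-Ctrl). PNO1 is a nucleolar protein needed for the maturation of 18S ribosomal RNA and the small ribosomal subunit. Each group held 3 samples, and each sample was hybridised to 1 Affymetrix expression array, 6 arrays in all. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. The median intensity lay between 25.6 and 25.9 on every array. Over all probe sets the log2 values correlated at r = 0.9981 to 0.9987 within a group and at 0.9916 to 0.9929 between groups, and the first principal component carried 76.2% of the variance. On the sh-PNO1 replicate 2 array the 3' probe set of ACTB exceeded the 5' probe set by 2.25 on the log2 scale, against 1.73 to 1.87 on the other 5 arrays, a sign of RNA quality. The same difference for GAPDH was small but separated the groups, −0.03 to −0.01 in sh-Ctrl and −0.08 to −0.06 in sh-PNO1. The number of arrays limits the precision of every value below.

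The first comparison asked how far the hairpin lowered its target. All 3 PNO1 probe sets fell. The brightest went from an intensity of 534 ± 1.7 (SD, n = 3) in sh-Ctrl to 106 ± 1.98 (SD, n = 3) in sh-PNO1, so that 19.9% of the control signal remained (log2 fold change −2.33 ± 0.04 SE, limma adjusted p = 1.89e-07). The second probe set went from 211 ± 0.72 to 61.2 ± 1.37 and kept 29.1% of the control signal. The third went from 229 ± 0.10 to 65.8 ± 1.54 and kept 28.7%. In each probe set all 3 sh-PNO1 arrays lay below all 3 sh-Ctrl arrays, for which an exact two-sided permutation test gives p = 0.1, the smallest value that 3 arrays against 3 allow. NOB1, the endonuclease that works with PNO1 at the 3' end of 18S rRNA, rose slightly (log2 fold change 0.24 ± 0.04 SE, adjusted p = 0.00275).

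**Figure D1:**
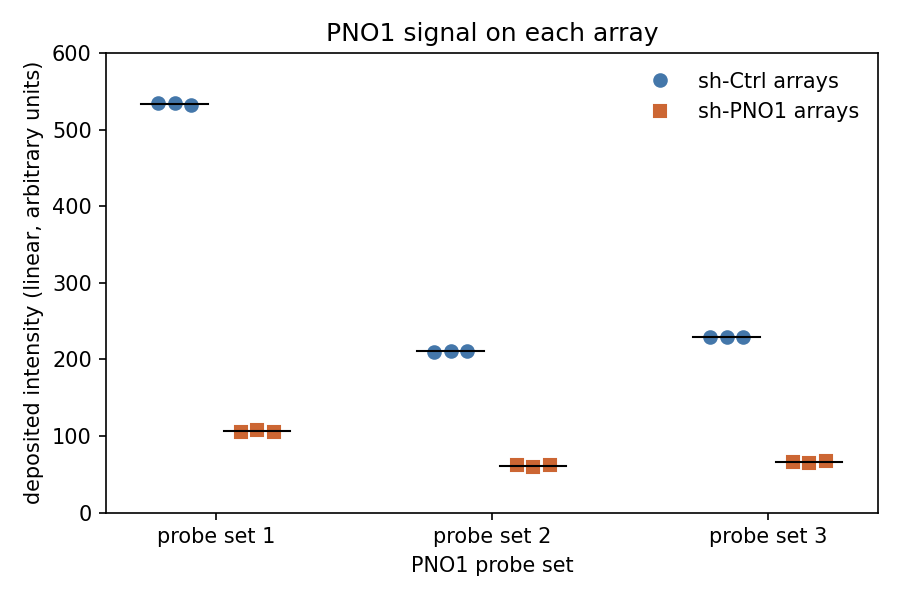
Intensity (linear, arbitrary units) of the 3 PNO1 probe sets on each array. Circles are the 3 sh-Ctrl arrays, squares the 3 sh-PNO1 arrays and lines the group means; the means of the first probe set are 534 and 106, and in every probe set the sh-PNO1 arrays lie below the sh-Ctrl arrays.

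The second comparison asked which transcripts differed between the groups. The largest increases among named genes were those of KRTAP2-3, a keratin-associated protein (log2 fold change 2.14 ± 0.06 SE), and ARL2BP, a binding partner of a small GTPase (2.03 ± 0.04 SE, intensity 196 ± 5.56 to 802 ± 8.05). RCHY1, a ubiquitin ligase, rose by 1.74 and KLHL28 by 1.71, each with both of its probe sets higher. H2BC5, a histone H2B gene, rose by 1.49 with 3 of 3 probe sets higher. SUN3 rose by 1.61, ALG5, an enzyme of N-glycosylation, by 1.36, GALNT5, which starts mucin-type O-glycans, by 1.35, the deubiquitinase YOD1 by 1.33 and SH3RF2 by 1.32. For PEX19, a peroxisome assembly factor, the probe set that represented the gene rose by 1.75, while its 4 probe sets ranged down to 0.07. The 4 probe sets of ARL2BP ranged down to −0.10, and only 1 of 3 for SH3RF2 rose, the lowest standing at 0.07. RPL27A rose by 1.72 on its only probe set, which was dim for a ribosomal protein gene (28.7 ± 3.16 to 94.3 ± 5.19).

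Apart from PNO1, the largest decreases were those of LSM6, a subunit of the ring that binds U6 small nuclear RNA (log2 fold change −2.50 ± 0.04 SE, intensity 562 ± 10.1 to 99.0 ± 3.78), MXRA7 (−2.34 ± 0.05 SE) and GLO1, the glyoxalase that detoxifies methylglyoxal (−2.21 ± 0.05 SE, 4 of 4 probe sets lower). The mitochondrial carrier SLC25A40 changed by −2.18, the F-box protein FBXO4 by −2.11, MSN (moesin, which ties actin to the plasma membrane) by −1.83, TBC1D8B by −1.82 and the small GTPase RAB26 by −1.80. The phosphoinositide phosphatase MTMR2 changed by −1.77 (4 of 4 probe sets lower), WSB2 by −1.76 (4 of 4) and LSM14A, a component of cytoplasmic RNA granules, by −1.71 (6 of 6). Not every probe set of these genes moved as far: those of FBXO4 ranged up to −0.003, those of MSN up to −0.08, those of TBC1D8B up to −0.10, those of MXRA7 up to −0.22 and those of SLC25A40 up to −0.50. These 12 increases and, with PNO1, 12 decreases all had limma adjusted p-values of 1.72e-05 or lower.

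Of 18132 genes tested, 6185 passed an adjusted p of 0.05 in limma, 3619 of them higher and 2566 lower in sh-PNO1. Most of these changes were small, with a median size of 0.31 on the log2 scale among the genes that passed. At least 2-fold changes were fewer, 57 higher and 133 lower, 190 in all. In 8106 genes (44.7%) the 3 sh-PNO1 arrays lay wholly above or below the 3 sh-Ctrl arrays, where chance gives 10%. The 2-fold count depended on how the probe sets of a gene were combined: it was 94 when they were averaged and 275 (76 higher, 199 lower) when the most variable probe set represented each gene.

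**Figure D2:**
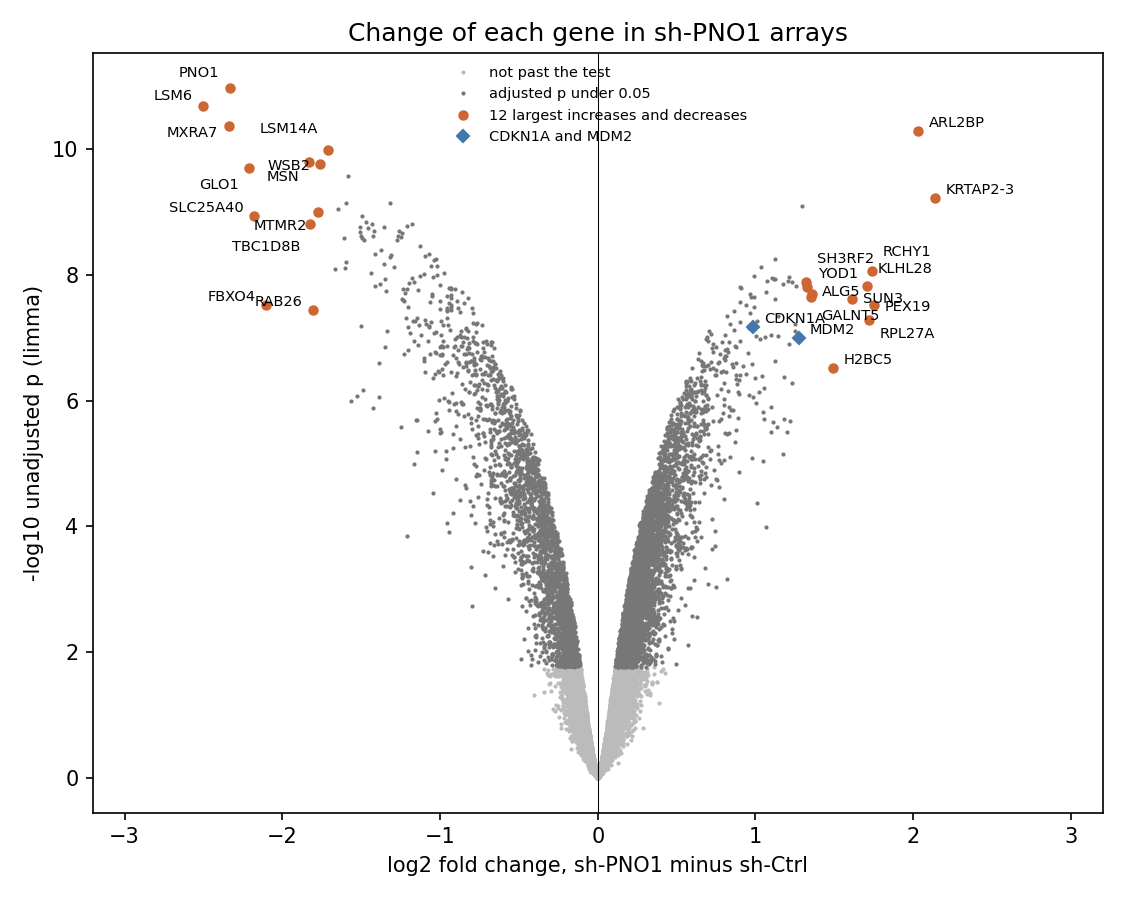
Each point is 1 of 18132 genes: log2 fold change (sh-PNO1 minus sh-Ctrl) against −log10 of the unadjusted limma p. Dark points passed an adjusted p of 0.05; orange circles mark the 12 largest increases and 12 largest decreases of the naming rule, led by KRTAP2-3 (2.14) and LSM6 (−2.50), and diamonds mark CDKN1A (0.99) and MDM2 (1.28).

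CDKN1A, the cyclin-dependent kinase inhibitor that halts the cell cycle, rose from 1438 ± 22.0 to 2852 ± 156 (log2 fold change 0.99 ± 0.05 SE, adjusted p = 7.38e-06). MDM2, a ubiquitin ligase induced in the same stress response, rose by 1.28 ± 0.07 SE (adjusted p = 9.55e-06), with 10 of its 11 probe sets higher. They belong to a list of growth arrest, DNA repair and apoptosis genes of which 52 were measured. In this list 37 genes rose and 2 fell over all genes tested, and 40 rose and 3 fell adjusted over the list alone; the median log2 fold change was 0.40. PLK2, a polo-like kinase, rose by 1.14, CYFIP2 by 0.99 (3 of 4 probe sets, down to −0.01), BBC3, a BH3-only promoter of apoptosis, by 0.70 and SESN2, a sestrin, by 0.57. KITLG, the ligand of the KIT receptor (−0.64, 1 of 4 probe sets lower), and ANKRA2 (−0.43), which were named after their values were seen, were the 2 that fell. The list shifted upward against all other genes in camera (adjusted p = 4.85e-11), a call that was lost with an estimated correlation between genes (adjusted p = 0.223).

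Genes of DNA replication and S phase fell together. Of 45 measured, 40 fell and 2 rose over all genes tested, and 41 fell and 2 rose adjusted over the list alone, with a median log2 fold change of −0.42 (camera adjusted p = 5.33e-21; adjusted p = 0.223 with an estimated correlation). GINS1, a subunit of the replicative helicase complex, changed by −1.31 ± 0.05 SE, the clamp loader subunit RFC5 by −1.26 ± 0.04 SE, the helicase subunit MCM2 by −1.13 ± 0.06 SE and the polymerase epsilon subunit POLE2 by −0.93 ± 0.04 SE. The 2 that rose, named after their values were seen, were MCM6 (0.58, 2 of 3 probe sets), another subunit of the MCM helicase, and CCNE1, cyclin E1 (0.23); CCNE1 did not pass without probe sets that can match several transcripts (0.06, adjusted p = 0.523). Genes of mitosis and the G2/M transition were also lower. Of 40 measured, 29 fell and 1 rose, 34 and 1 adjusted over the list alone, with a median of −0.32 (camera adjusted p = 2.92e-14; adjusted p = 0.307 with an estimated correlation). ANLN, a cytokinesis scaffold, changed by −0.76, the kinesin CENPE by −0.68, CDCA8, a subunit of the chromosomal passenger complex, by −0.65 and HMMR by −0.60. The gene that rose, MKI67, did so only on its brightest probe set (0.22): 5 of its 6 probe sets fell, and the mean of all 6 changed by −0.59 (adjusted p = 7.09e-05).

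Endoplasmic reticulum (ER) genes of the unfolded protein response fell. Of 27 measured, 20 fell and 2 rose, 21 and 2 adjusted over the list alone, with a median of −0.37 (camera adjusted p = 1.01e-09; adjusted p = 0.0729 with an estimated correlation). The co-chaperone DNAJC3 changed by −0.83 ± 0.05 SE, SDF2L1 by −0.82 ± 0.05 SE, the ER chaperone HYOU1 by −0.77 ± 0.04 SE (5 of 9 probe sets lower) and the secreted factor MANF by −0.69 ± 0.04 SE. The 2 that rose, named after their values were seen, were the ER-associated degradation genes DERL1 (0.58) and DERL2 (0.13). Neither held throughout: 2 of the 3 DERL1 probe sets fell and their mean did not pass (0.02, adjusted p = 0.734), and DERL2 did not pass when any array but sh-PNO1 replicate 1 was left out, with an adjusted p of up to 0.0874 (without sh-Ctrl replicate 3).

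Among feedback regulators of the MAPK pathway and immediate early genes, 13 of 23 measured fell and 3 rose, 13 and 5 adjusted over the list alone, with a median of −0.16 (camera adjusted p = 0.0016; adjusted p = 0.223 with an estimated correlation). SPRY4, an inhibitor of receptor tyrosine kinase signalling, changed by −1.17 ± 0.05 SE (probe sets up to −0.06), IER3 by −0.79 ± 0.04 SE and the MAPK phosphatase DUSP4 by −0.73 ± 0.04 SE. The transcription factor gene JUN went the other way (0.96 ± 0.07 SE, 4 of 4 probe sets higher), as did SPRY1 (0.35) and EGR1 (0.30), which were named after their values were seen.

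Nuclear genes of mitochondrial respiration rose by small amounts. Of 49 oxidative phosphorylation genes measured, 31 rose and 2 fell, 36 and 2 adjusted over the list alone, with a median log2 fold change of 0.16 (camera adjusted p = 6.97e-07; adjusted p = 0.223 with an estimated correlation). NDUFA8, a complex I subunit, rose by 0.41 ± 0.05 SE, NDUFA10, another one, by 0.36, the complex III subunit UQCRC1 by 0.35 ± 0.04 SE and the complex II subunit SDHD by 0.32 ± 0.04 SE. COX8A (−0.19) and ATP5F1C (−0.13), named after their values were seen, fell; ATP5F1C did not pass when any array but sh-PNO1 replicate 1 was left out, with an adjusted p of up to 0.0937 (without sh-Ctrl replicate 3), nor with its probe sets averaged (−0.003, adjusted p = 0.969). Of 75 mitochondrial ribosomal proteins, 33 rose and 7 fell, 37 and 8 adjusted over the list alone, with a median of 0.12 (camera adjusted p = 0.00186; adjusted p = 0.223 with an estimated correlation). MRPL4 rose by 0.48, MRPS30 by 0.44, MRPL49 by 0.41 and MRPS18C by 0.38. This list also lost its call when the most variable probe set represented each gene (adjusted p = 0.107).

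The remaining 3 lists that camera called were weaker. In cholesterol synthesis 7 of 19 genes fell and 1 rose, the same counts as adjusted over the list alone, with a median of −0.08 (adjusted p = 0.0332; adjusted p = 0.33 with an estimated correlation). Those that fell included the isopentenyl diphosphate isomerase IDI1 (−0.89), the transcription factor gene SREBF2 (−0.45, 1 of 3 probe sets lower, up to −0.04), the synthase HMGCS1 (−0.43) and INSIG1 (−0.40). PMVK, phosphomevalonate kinase, rose (0.21) but did not pass when any array but sh-PNO1 replicate 1 was left out, with an adjusted p of up to 0.124. In fatty acid synthesis 7 of 15 fell and 3 rose, again the same counts adjusted over the list alone, with a median of −0.08 (adjusted p = 0.0497; adjusted p = 0.347 with an estimated correlation). The desaturase SCD changed by −0.68 and ACLY, which makes cytosolic acetyl-CoA, by −0.51 and the elongase ELOVL5 by −0.34, while ELOVL6 rose by 0.38. MLXIPL (0.22) and ACSL1 (0.12) also rose, but MLXIPL did not pass when any array but sh-PNO1 replicate 2 was left out (adjusted p up to 0.105), nor ACSL1 when any but sh-PNO1 replicate 1 was (up to 0.0777). With its probe sets averaged ACSL1 stood at −0.06 (adjusted p = 0.408). Of 22 NRF2 antioxidant genes 8 fell and 1 rose, 9 and 1 adjusted over the list alone, with a median of −0.06 (adjusted p = 0.0417; adjusted p = 0.385 with an estimated correlation). The quinone reductase NQO1 changed by −0.74, the transporter ABCC3 by −0.72 and GCLC, the catalytic subunit for glutathione synthesis, by −0.36, while the heme oxygenase HMOX1 rose by 1.04 ± 0.07 SE. ABCC3 stood at −0.23 (adjusted p = 0.112) without probe sets that can match several transcripts. Other settings ended these calls in many cases. On ranks the adjusted p was 0.0705 for cholesterol, 0.123 for fatty acid and 0.0705 for NRF2 genes, and without the dimmest 30% of genes 0.0567, 0.062 and 0.0623. With the most variable probe set it was 0.102 for cholesterol and 0.0505 for NRF2 genes, and without probe sets that can match several transcripts 0.101 and 0.0974. With probe sets averaged it was 0.072 for cholesterol genes. Quantile normalisation repeated gave 0.0565 and equal array medians 0.0534 for fatty acid genes. Without sh-Ctrl replicate 1 the adjusted p was 0.0606 for cholesterol, 0.0707 for fatty acid and 0.0712 for NRF2 genes, and without sh-PNO1 replicate 2 it was 0.0793, 0.0976 and 0.093. Without sh-Ctrl replicate 3 it was 0.061 for fatty acid and 0.0522 for NRF2 genes, and without sh-PNO1 replicate 3 it was 0.0587 for fatty acid genes.

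**Figure D3:**
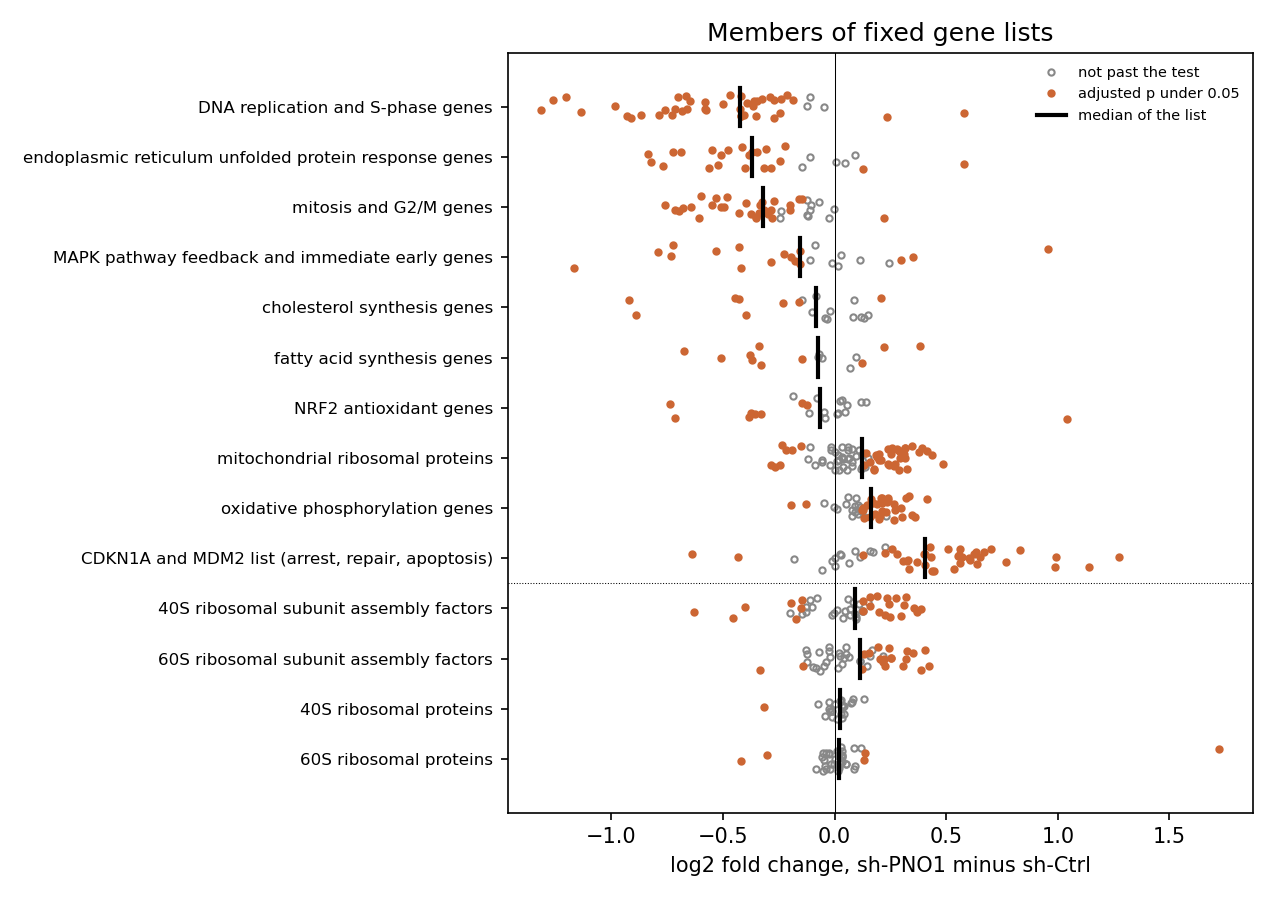
Log2 fold change (sh-PNO1 minus sh-Ctrl) of each measured member of the 10 gene lists that camera called, above the dotted line, and of 4 ribosome lists that it did not call, below it. Filled points passed an adjusted p of 0.05 and bars are list medians, from −0.42 for DNA replication to 0.40 for the list of CDKN1A and MDM2.

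Genes of the ribosome itself changed little. Of 23 small-subunit ribosomal proteins measured, 1 fell and none rose in limma, also when adjusted over the list alone, with a median of 0.02 (camera adjusted p = 0.993). The gene that fell was FAU (−0.32 ± 0.04 SE, 3 of 3 probe sets lower); RPS19 stood at 0.13 (adjusted p = 0.0654), and RPS9 and RPS7 at 0.08 each (adjusted p = 0.138 and 0.159). RPS19 passed as higher under 5 alternatives, among them probe sets averaged (0.20, adjusted p = 0.00882) and a mean-variance trend with a robust prior (adjusted p = 0.0055), and RPS9 (0.0152) and RPS7 (0.0153) passed under the latter. The median and mean of this list were above 0 while the test, which compares it with all other genes, pointed down. Of 41 large-subunit ribosomal proteins 3 rose and 2 fell, 1 and 1 adjusted over the list alone, with a median of 0.02 (adjusted p = 0.993). RPL13 changed by −0.42 ± 0.04 SE, against 1.72 for the dim RPL27A probe set. RPL35A changed by −0.30, and RPL8 (0.13) and RPL14 (0.14) rose slightly, but each of these 3 failed to pass with several single arrays left out, with an adjusted p of up to 0.0909, 0.0658 and 0.0942. RPL14 stood at −0.03 (adjusted p = 0.822) without probe sets that can match several transcripts.

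Assembly factors of the small subunit went both ways. Of 47 measured, 17 rose and 7 fell, 19 and 8 adjusted over the list alone, with a median of 0.09 (camera adjusted p = 0.438). The kinase RIOK1 changed by −0.63 ± 0.05 SE, the processome component WDR36 by −0.46 ± 0.05 SE and TSR1 by −0.40 ± 0.04 SE (its other probe set 0.05). The kinase RIOK2 rose by 0.37 ± 0.04 SE. Of 46 large-subunit assembly factors 18 rose and 2 fell, 21 and 3 adjusted over the list alone, with a median of 0.11 (adjusted p = 0.0659, 0.0446 without sh-PNO1 replicate 3 and 0.0297 with a mean-variance trend and robust prior). ZNF622 rose by 0.42, GNL3L by 0.41, LAS1L by 0.39 and the helicase DDX54 by 0.31; with probe sets averaged neither LAS1L (adjusted p = 0.0601) nor DDX54 (0.06, adjusted p = 0.237) passed. The 2 that fell were RRP1B (−0.33) and RRS1 (−0.14): RRP1B stood at 0.06 (adjusted p = 0.486) without probe sets that can match several transcripts, and RRS1 did not pass with some single arrays left out (adjusted p up to 0.0758). Of 24 small nucleolar ribonucleoprotein and nucleolar proteins 6 rose and 1 fell, the same adjusted over the list alone, with a median of 0.07 (adjusted p = 0.24). NAF1, an H/ACA assembly factor, rose by 0.39, the ATPase RUVBL2 by 0.31, MYBBP1A by 0.30 and SURF6 by 0.20; MYBBP1A did not pass without probe sets that can match several transcripts (adjusted p = 0.0889). NUFIP1 fell (−0.15), but not with some single arrays left out (adjusted p up to 0.0797). Of 30 subunits and factors of RNA polymerases I and III 10 rose and 6 fell, 12 and 6 adjusted over the list alone, with a median of 0.08 (adjusted p = 0.812). Those that fell included GTF3C2 (−0.86, probe sets up to 0.14), the polymerase I initiation factors RRN3 (−0.49), TAF1A (−0.45) and UBTF (−0.34). Of 39 translation factors 14 rose and 4 fell, the same adjusted over the list alone, with a median of 0.08 (adjusted p = 0.163); EIF3G rose by 0.57 (2 of 4 probe sets, down to −0.23), EIF3D by 0.42, EIF2S1 by 0.37 and EIF2B2 by 0.36. Those that fell were EIF3L (−0.30), EIF2B3 (−0.23), EIF3F (−0.16) and EIF3E (−0.14); EIF3F did not pass with probe sets averaged (−0.07, adjusted p = 0.193), nor EIF3E with any array but sh-PNO1 replicate 1 left out (adjusted p up to 0.136). Of 30 MYC target genes 11 rose and 4 fell, 12 and 4 adjusted over the list alone (adjusted p = 0.845). Their median was −0.002 while their mean and the test pointed up; SRM, spermidine synthase, rose by 0.48 and TMEM97 changed by −1.18, the mitochondrial chaperonin HSPE1 by −0.40, the cyclin-dependent kinase CDK4 by −0.20 and LDHA by −0.13. LDHA did not pass when any array but sh-PNO1 replicate 2 was left out (adjusted p up to 0.093). PHB1 rose by 0.25, but stood at −0.04 (adjusted p = 0.542) without probe sets that can match several transcripts. Of 8 small nucleolar RNA host genes 1 rose and 1 fell, also adjusted over the list alone, with a median of 0.02 (adjusted p = 0.993): EPB41L4A-AS1 (0.20; adjusted p up to 0.0834 with 1 array left out) and SNHG8 (−0.22). SNHG7 and TAF1D stood at 0.08 each (adjusted p = 0.222 and 0.341). Of the lists of this and the previous paragraph, none called by camera in the planned fit, fry called 5 as higher in one direction: small-subunit assembly (adjusted p = 0.00558), large-subunit assembly (0.000955), nucleolar proteins (0.00192), translation factors (0.00665) and large-subunit ribosomal proteins (0.0396).

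Of 31 BCL2 family and apoptosis genes 10 rose and 5 fell, the same adjusted over the list alone, with a median of 0.02 (adjusted p = 0.651). Besides BBC3, the inhibitor of apoptosis BIRC2 rose by 0.59 and DIABLO changed by −0.65, the death receptor TNFRSF10A by −0.51 and the caspases CASP6 by −0.22 and CASP2 by −0.16. CASP2 did not pass without probe sets that can match several transcripts (adjusted p = 0.162). MCL1, an anti-apoptotic member, changed by −0.93 ± 0.04 SE, but its 6 probe sets ranged from −0.98 to 0.17, and without probe sets that can match several transcripts it stood at 0.17 (adjusted p = 0.0703). Of 34 genes of ATF4 and the integrated stress response 15 rose and 7 fell, 16 and 7 adjusted over the list alone, with a median of 0.08 (adjusted p = 0.412); ATF3 rose by 0.95 (4 of 7 probe sets) and the amino acid transporter SLC7A5 changed by −0.87 (its other probe set −0.16) and JDP2 by −0.48. Of 18 heat shock genes 6 rose and 5 fell, 6 and 7 adjusted over the list alone, with a median of −0.01 (adjusted p = 0.635). HSPA4L rose by 0.82 and the co-chaperone FKBP4 by 0.42, while HSPB1 changed by −0.58, HSPE1 by −0.40, HSPH1 by −0.30, DNAJA1 by −0.30 and HSPA1B by −0.22. Of 33 type I interferon response genes 12 rose and 1 fell, also adjusted over the list alone, with a median of 0.07 (adjusted p = 0.0697); the exonuclease ISG20 rose by 0.86, IFIT2 by 0.75 (its other probe set 0.10), the RNA sensor IFIH1 by 0.59 (the other 0.009) and ISG15 by 0.57, and PARP9 changed by −0.37. Of 29 NF-kB and inflammatory genes 3 rose and 7 fell, also adjusted over the list alone, with a median of −0.003 (adjusted p = 0.315). TNFAIP3, a brake on NF-kB signalling, rose by 0.69, and the cytokine LIF changed by −0.68 (probe sets up to −0.17) and the urokinase receptor PLAUR by −0.53. The others that rose were TNFAIP2 (0.40) and IL6 (0.22, intensity only 11.1 to 12.9). TNFAIP2 stood at −0.13 (adjusted p = 0.105) without probe sets that can match several transcripts, and IL6 did not pass with some single arrays left out (adjusted p up to 0.0591). Of 30 hypoxia and glycolysis genes 9 rose and 6 fell, also adjusted over the list alone, with a median of 0.05 (adjusted p = 0.971); P4HA1 changed by −0.91, while the peptide ADM rose by 0.49, ENO2, an enolase, by 0.40 and GPI by 0.39. Of 33 lysosome and autophagy genes 11 rose and 7 fell, 12 and 7 adjusted over the list alone, with a median of 0.09 (adjusted p = 0.635). The autophagy gene MAP1LC3B rose by 0.73 and the proton pump subunit ATP6V1A by 0.34, and NPC2 changed by −0.40 and the protease CTSL by −0.37. Of 27 proteasome subunits 3 rose and 5 fell, also adjusted over the list alone, with a median of 0.005 (adjusted p = 0.482); PSMA2 changed by −1.03 with both probe sets lower, PSMD14 by −0.54, PSMA7 by −0.33, PSMB5 by −0.29 and PSMA1 by −0.22. PSMA1 stood at 0.08 (adjusted p = 0.152) with probe sets averaged. PSMC4 rose by 0.28, PSMD8 by 0.27 and PSMC3 by 0.16; PSMC3 did not pass without sh-Ctrl replicate 2 (adjusted p = 0.0519). Of 21 purine and pyrimidine synthesis genes 4 rose and 7 fell, 6 and 8 adjusted over the list alone, with a median of −0.05 (adjusted p = 0.2). ADSL, a purine synthesis lyase, changed by −0.49 (its other probe set 0.13) and DHODH, of pyrimidine synthesis, by −0.40. The 4 that rose were PFAS (0.23), APRT (0.22), CTPS1 (0.14) and PRPS1 (0.13). PFAS did not pass with probe sets averaged (0.09, adjusted p = 0.116), where CTPS1 turned to −0.14 (adjusted p = 0.0277). With some single arrays left out CTPS1 (adjusted p up to 0.0959) and PRPS1 (up to 0.0796) did not pass. Camera called none of the lists of this paragraph in the planned fit, but with probe sets averaged it called the interferon (adjusted p = 0.049) and the purine and pyrimidine (0.0496) lists. Fry in one direction called 7 of them: apoptosis (adjusted p = 0.00192), ATF4 (0.00275), interferon (0.00179), hypoxia (0.0365) and lysosome genes (0.0351) as higher, NF-kB (0.00192) and purine and pyrimidine genes (0.00145) as lower.

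Camera did not call lists of intestinal identity and cell shape either. Of 21 Wnt and stem cell genes 1 rose, NKD1 (1.22, 2 of 4 probe sets), and 3 fell, cyclin D1, CCND1 (−0.39, 4 of 4 probe sets lower), ETS2 (−0.25) and CD44 (−0.24), the same adjusted over the list alone; the median (−0.0008) and the test pointed down and the mean up (adjusted p = 0.635). Of 31 enterocyte and secretory genes 2 rose and 2 fell, none and 2 adjusted over the list alone, with a median of 0.05 (adjusted p = 0.993). CA2, a carbonic anhydrase (−0.22), fell, and CHGA, chromogranin A, was the other counted as lower (−0.23). FABP2 (0.22, intensity 4.87 to 5.68) and the mucin MUC2 (0.20, intensity 8.02 to 9.22), the 2 counted as higher, were dim, as was CHGA (11.2 to 9.54); like every gene below the brightest background probe set, they could not be judged against background. FABP2 and MUC2 did not pass with some single arrays left out (adjusted p up to 0.114 and 0.105). Of 25 epithelial adhesion genes 8 rose and 6 fell, also adjusted over the list alone (adjusted p = 0.989), and the laminin subunit LAMB3 rose by 1.25 (its other probe set −0.009), plakoglobin, JUP, by 0.42 and the keratin KRT19 by 0.37, and the desmosomal cadherin DSC2 changed by −0.33. Of 29 mesenchymal and matrix genes 8 rose and 3 fell, 9 and 3 adjusted over the list alone, with a median of 0.07 (adjusted p = 0.392). The matrix protein gene THBS1 rose by 1.12 (4 of 5 probe sets) and the collagen COL6A1 by 0.58 (4 of 6), and CCN2 changed by −0.68, TWIST1 by −0.53 and vimentin, VIM, by −0.27 (intensity only 14.8 to 12.3); ACTA2 rose by 0.88, but stood at −0.11 (adjusted p = 0.151) without probe sets that can match several transcripts. Of 20 histone genes 6 rose and 4 fell, 6 and 6 adjusted over the list alone (adjusted p = 0.989). Besides H2BC5, H2BC12 rose by 0.94 (its other probe set −0.20), while H2AC20 changed by −0.87, H2AX by −0.53, H1-4 by −0.35 and H4C3 by −0.13. H4C3 did not pass when any array but sh-PNO1 replicate 2 was left out (adjusted p up to 0.117). For the adhesion and the histone lists the median (−0.009 and −0.006) and the test pointed down and the mean up. Fry called the mesenchymal (adjusted p = 0.00267), adhesion (0.0396) and histone (0.0396) lists as higher in one direction.

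Camera called none of the 4 lists of markers of other cell types. Of 15 leukocyte markers 1 fell, FCER1G (−0.22, intensity only 18.3 to 15.8, and not past the threshold without sh-Ctrl replicate 2, sh-Ctrl replicate 3, sh-PNO1 replicate 1 or sh-PNO1 replicate 3, with an adjusted p of up to 0.077), and none rose; the median was 0.01 (adjusted p = 0.971). TYROBP stood at −0.15 (adjusted p = 0.0688), CD3E at 0.16 (0.104) and CD14 at 0.13 (0.269). None of 13 fibroblast markers passed in limma, and the median was 0.02 (adjusted p = 0.993). COL1A2 stood at 0.24 (adjusted p = 0.0511), DCN at −0.31 (0.083), PRRX1 at 0.16 (0.177) and TWIST2 at 0.24 (0.283). Under alternatives COL1A2 passed in 7 (adjusted p down to 0.0212), DCN in 4 (down to 0.0272), TYROBP in 2 (down to 0.0436) and CD3E in 1 (0.044). For these 2 lists the median and mean were above 0 while the test pointed down. Of 12 endothelial markers 1 rose, TIE1 (0.26, and not past the threshold without any 1 array other than sh-Ctrl replicate 2, with an adjusted p of up to 0.133), with a median of 0.04 (adjusted p = 0.845). PECAM1 and CDH5 stood at 0.12 each (adjusted p = 0.134 and 0.147) and VWF at 0.07 (0.365), and each of PECAM1 (0.0198) and CDH5 (0.0463) passed with a single array left out, and VWF with the most variable probe set (adjusted p = 0.0366). Of 9 markers of embryonic kidney cells, a common source of lentivirus, none passed, with a median of 0.14 (adjusted p = 0.438 in camera), but fry called this list as higher in one direction (adjusted p = 0.0396). LHX1 stood at 0.22 (adjusted p = 0.0796), GATA3 at 0.19 (0.0678), HOXD10 at 0.17 (0.067) and EYA1 at 0.16 (0.0682). Under alternatives GATA3 passed in 5 (adjusted p down to 0.0239), EYA1 in 3 (down to 0.0291), HOXD10 in 3 (down to 0.0302) and LHX1 in 2 (down to 0.0312). Adjusted over each list alone, no marker of the 4 lists passed. Among 14 housekeeping reference genes 2 rose and 3 fell, 2 and 4 adjusted over the list alone, with a median of −0.005 (adjusted p = 0.635). The transferrin receptor TFRC rose by 0.57 (2 of 3 probe sets) and ALAS1 by 0.21, and IPO8 changed by −0.35, TUBB by −0.29 and YWHAZ by −0.15. YWHAZ did not pass with any 1 array left out (adjusted p up to 0.122). In all, camera called 10 of 38 lists with its preset correlation, 3 higher and 7 lower, and 0 with an estimated one. Fry, which asks only whether a list moves one way, called 26. The ER list lost its camera call at an estimated correlation of −0.0178 and the MAPK list at 0.0117, against the preset 0.01. Correlation between genes alone therefore does not account for the lost calls of these lists. The setting with an estimated correlation must change more than the correlation itself. A call lost under it does not by itself show that the genes of a list are correlated.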

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

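Outside the gene test lay 4305 probe sets that are not listed in the gene table or carry several symbols, 593 of them higher and 498 lower in sh-PNO1. Only 3 were at least 2-fold higher and 20 at least 2-fold lower, and the 3 are given here because a signal above the control arrays appeared in probe sets that no comparison used. An unlisted probe set rose by 1.143 on the log2 scale (intensity 103 ± 2 to 227 ± 5.71, SD, n = 3; limma adjusted p = 3.55e-06), and a second unlisted one by 1.029 (45.8 ± 1.59 to 93.5 ± 2.24; adjusted p = 6e-06). A probe set shared by CKMT1A and CKMT1B, the near-identical genes of ubiquitous mitochondrial creatine kinase, rose by 1.13 (54.9 ± 9.12 to 119 ± 1.47; adjusted p = 0.000141), and which of the 2 genes it reports cannot be read from it. Each of the 3 rested on 3 arrays per group.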

How the results depend on the processing

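The alternative without _x_at and _s_at probe sets was chosen after seeing the data. PNO1 kept its direction and its call under every alternative run, from −2.35 to −1.97 on the log2 scale. Leaving out 1 array gave 5119 to 5545 genes that passed (2952 to 3238 higher, 2167 to 2314 lower), 184 to 204 at least 2-fold (52 to 59 higher, 127 to 145 lower), 7 to 10 lists called and −2.35 to −2.32 for PNO1. With every probe set tested 12716 passed (6720 higher, 5996 lower) and 426 were at least 2-fold (98 higher, 328 lower), because more features are counted. With probe sets averaged 94 genes were at least 2-fold (24 higher, 70 lower); treat against 0.5 called 451 (144 higher, 307 lower), by its lower bound; and at an adjusted p under 0.01 there were 2364 genes higher and 4187 in all. Camera called 0 lists with an estimated correlation, and fry called 26 in one direction and 35 in its mixed form, which asks another question. Fry called the adhesion (median −0.0092) and histone (median −0.0064) lists as higher, where camera pointed down without a call. Named genes that had passed and changed sign were, with probe sets averaged, MKI67 (−0.59), ACSL1 (−0.0556), PSMA1 (0.083), CTPS1 (−0.14), MAPK9 (0.0961) and SMAD2 (−0.2457); with the largest interquartile range, MKI67 (−0.89), NUP98 (0.5831), RPL14 (−0.0338), ACSL1 (−0.2342), PSMA1 (0.383), CTPS1 (−0.366), MAPK9 (1.91) and SMAD2 (−0.96); and without _x_at and _s_at probe sets, MCL1 (0.17), ACTA2 (−0.11), RRP1B (0.0575), RPL14 (−0.0338), ACSL1 (−0.2342), TNFAIP2 (−0.1324) and PHB1 (−0.0435). Of named genes that had not passed, LHX1 (−0.0228 with probe sets averaged, −0.1841 with the largest range), CD3E (−0.0665 with the largest range), PECAM1 (−0.0671 with it and without _x_at and _s_at probe sets) and SNHG7 (−0.0197 without them) also changed sign, with no call. These came from another probe set of the same gene. Reasons why probe sets of a gene differ were tested only for genes with probe sets that passed in opposite directions, as given below. Besides PNO1, 226 genes were followed: those of the naming rule and others that the text names, which were added after their values were seen. Of their 3578 values under alternatives 3363 kept direction and side of the threshold, and 169 of the 226 genes did so throughout. The share of higher genes was 58.5%, and 57 to 63.5% over the scaling alternatives, which moved the median of all genes by at most 0.017. The deviations of same-numbered arrays correlated only at −0.036, 0.097 and −0.032, so no effect shared by replicate number was visible. The labels do not say what a number shares, so whether the arrays were paired is unknown. A fit with the replicate number as a block called 5848 genes, 190 of them 2-fold, and 9 lists, without the fatty acid list. Of the genes named, 164 lay at or below the brightest background probe set and 63 above it.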

Other observations

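Among groups of genes that share a symbol stem, 320 groups of 8 or more measured genes were tested with camera after the lists above had been seen, and 5 passed. Nucleoporins, the building blocks of the nuclear pore, were lower: of 24 genes with the stem NUP 12 fell and none rose in limma, with a median log2 fold change of −0.11 (camera adjusted p = 0.00232; adjusted p = 0.981 with an estimated correlation). NUP210 changed by −1.01 ± 0.06 SE (its other probe set −0.28) and NUP153 by −0.52 ± 0.05 SE, while the probe sets of NUP98 ranged from −0.48 to 0.58. Inositol polyphosphate phosphatases were higher: 8 of 9 INPP genes rose and none fell, with a median of 0.30. Camera gave an adjusted p of 0.02, and of 0.981 with an estimated correlation. INPP5A (0.73 ± 0.04 SE, 3 of 4 probe sets) and INPP4B (0.48 ± 0.04 SE, 3 of 6, down to −0.23) led the group. Of 35 VPS genes, which sort vesicles to endosomes and lysosomes, 20 rose and 3 fell, with a median of 0.16 (adjusted p = 0.036; adjusted p = 0.981 with an estimated correlation). VPS26B, a retromer subunit, rose by 0.70 and VPS36 by 0.52 (4 of 8 probe sets), while VPS52 changed by −0.63 (4 of 6). The other 2 groups were MCM and NDUFA, which overlap with the replication and respiration lists and were lost with an estimated correlation too (adjusted p = 0.981).

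The tests of the 18S pattern and the test of a shift of all genes were chosen only after the result was seen; the other tests were written before. The Wilson margins around the percentages were added after the values were seen. Like the resampling of genes below, they take genes as independent and do not measure the spread between arrays. The array carries control probe sets for ribosomal RNA. All 3 probe sets for 18S rRNA were lower in sh-PNO1, by −0.33 ± 0.08 SE at the 3' end (adjusted p = 0.018), −0.44 ± 0.05 SE in the middle (adjusted p = 0.000597) and −0.32 ± 0.06 SE at the 5' end (adjusted p = 0.00384), and their arrays did not overlap between groups. The 18 probe sets for hybridisation spikes, added in equal amounts, differed by −0.0036 on average (lowest −0.09), which argues against a difference in scaling between arrays as large as the 18S change. For 28S rRNA the 5' probe set changed by −0.45 ± 0.07 SE, the middle one by 0.002 and the dim 3' one by 0.09. So 1 of 3 28S probe sets fell as far as those of 18S, which leaves less carry-over of all ribosomal RNA into the labelled cRNA open, and the mean of 18S minus 28S was −0.2447, which leaves open the hypothesis that less 18S rRNA, whose maturation needs PNO1, may have been present.

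More genes rose than fell (3619 against 2566), yet 70% of the at least 2-fold changes were decreases; if compressed folds of dim genes hid increases, the excess of decreases should vanish among bright genes, but among the brightest 6044 genes 74.1% of 2-fold changes were decreases (margin 65.3 to 81.3%). Decreases made up 66.7% or more (margin from 59.6%) under the 3 scaling alternatives, where the bound written beforehand was 60%. Raising all sh-PNO1 values by 0.13 (0.08 to 0.17 over resampled genes) would even out the 2-fold counts, which misses this test's bound of 0.1. The 18 hybridisation spike probe sets differed by −0.0036 on average (SD 0.0402 over probe sets), and singly by up to 0.092. The 24 labelling spike probe sets differed by 0.0128 on average (SD 0.079 over probe sets), and singly by −0.12 to 0.21. The highest of them, AFFX-LysX-M_at, passed in limma (adjusted p = 0.0294). A scaling difference would move all probe sets of a kind together, so these means argue against one as large as 0.13. The scaling test and the shift test missed their bounds by their margins alone, so a smaller scaling difference stays open. The test of dim genes met its bound with its margin. Open and untested are the biological difference between the groups and an effect of the hairpin on messages other than its target. The labels do not say how many hairpins were used, and no sequence is used here.

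In 56 of 1681 genes with 2 or more probe sets that passed with a change of at least 0.3 on the log2 scale (3.33%), the probe sets went in opposite directions. MAPK9 had one probe set at 1.91 ± 0.08 SE and another at −0.82 ± 0.05 SE, and SMAD2 stood at 0.66 ± 0.07 SE and −0.96 ± 0.08 SE. Cross-hybridisation of _x_at and _s_at probe sets is argued against as the main reason, since without them the rate was 41 of 1019 (4.02%), 1.208 times the rate with them. Dim probe sets may account for some cases: 23.2% of these genes had a probe set below the 30th percentile of mean value, which meets the bound of 25% written beforehand, but its margin (to 35.8%) does not. A change in transcript isoforms or in the end of the message was not tested, as probe positions were not used here.

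Because 3 arrays against 3 make only 10 splits, no share under 0.05 can be reached. The number of splits with a result as large, the real one included, was 1 for the genes that passed (6185, against a highest of 0 in any other split by limma, where up to 323 genes had an unadjusted p under 0.05), 1 for the 2-fold genes (190 against 0) and 1 for the lists (10 against 6). Each other split mixes the groups, so the difference between them adds to the spread within each set of 3 and keeps limma's calls low. The counts of 0 there therefore do not show what arrays without a group difference would give. Each other split also keeps 2 arrays of a group together, and the lists that changed most were called there too: the replication list, that of CDKN1A and MDM2 and the ER list in 9 of 9 other splits, mitosis in 8 of 9 and oxidative phosphorylation in 6 of 9. The mitochondrial ribosomal and MAPK lists were called in 2 of 9, and the fatty acid, NRF2 and translation factor lists in 1 of 9. Because 2 arrays of a group stay together, part of the group difference remains in every other split, and these calls cannot be read as false calls. Nor do they show that false calls are few, so the splits leave camera's p-values with the preset correlation unchecked. Of the 10 lists, 8 had a lower adjusted p in the real split than in every other.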
